A study of Mus musculus with 30 samples.

How the data were processed

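RNA from mouse kidney was measured by RNA sequencing in 30 libraries, 1 per animal, from animals homozygous or heterozygous for the db allele of Lepr, the leptin receptor gene, on 3 diets. Per the labels' protocols, total RNA was extracted from renal cortex with a DirectZol kit, ribosomal RNA was depleted, and stranded libraries were prepared with NEB kits. Per the submitters' processing notes, STAR and the builds mm10 and GRCm38 were used. The aligner version, the gene annotation, the counting tool, its strand setting and any filter of the authors are not given in the sources used here. The deposited table held raw read counts per gene, as whole numbers, for 48526 Ensembl genes and 30 libraries. Of these genes 17773 had no count in any library. Positions were taken from GENCODE M21, on GRCm38, which held 48058 of the identifiers.

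The labels gave 5 animals in each of 6 groups. In 2 libraries, heterozygous standard library 2 and heterozygous resistant starch library 3, the label gave whole kidney, and they were left out of the comparisons, which used the 28 renal cortex libraries. Libraries were numbered within each group in the order of the animal numbers. Differences between groups were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr by group (16131 genes), libraries were scaled by TMM, and 1 quasi-likelihood model with robust estimation held a mean for each group. P-values were adjusted by the Benjamini-Hochberg method within each of 11 comparisons, and a gene was called at an adjusted p under 0.05. Values per gene are CPM (counts scaled to a library total of 1e+06) on TMM-scaled library sizes, as mean and SD over the libraries of a group, and log2 fold changes come from the model. An interaction is a difference of log2 fold changes, homozygous minus heterozygous.

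Gene lists for pathways, kidney segments, other cell types and sex-biased genes, 42 in all, were fixed together with the comparisons, the tests, the naming of genes and all but 3 of the alternatives before the data were examined. The 41 lists with at least 3 tested genes were compared with all other genes by camera in limma 3.58.1, with the preset correlation of 0.01, on log2 CPM with a prior count of 2. They were tested again with an estimated correlation, with which 0 of the list calls held in any comparison (tool: camera). They were also tested with fry, which asks whether the genes of a list move on balance one way and compares them with no other genes. A score per list and library, the mean over its genes of the centred log2 CPM, was used to count the libraries that showed a list's direction, against the median of the other group.

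Genes were named by rule. In each comparison these were the 10 called genes with the largest increase and the 10 with the largest decrease, with a mean of at least 1 CPM in the higher group, no model or clone name and at least 75% of the libraries on their own side of the other group's median. For interactions 5 and 5 were named, without the last condition. Up to 4 genes of each list described were named, by adjusted p. Some genes so named are not reported here. Where fewer than 5 genes passed, the 5 smallest p-values were given as values. In every comparison 8 genes were read: C3, C5ar1, Ager, Havcr1, Lcn2, Nphs1, Slc5a2 and Col1a1. Lepr was read per group, but the db allele alters splicing, so its gene-level count does not check the genotype labels.

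The model was tested on simulated data of the same depth and group sizes, with known folds. For the heat-treated against the standard diet in homozygotes it recovered 57.6%, 83.6% and 98.5% of genes changed 1.5-, 2- and 4-fold. It made 7 false calls among 15699 unchanged genes. The shares were 71.9%, 83.6% and 95.3% for the same diets in heterozygotes, with 5 among 15738. They were 53.7%, 77.6% and 96.9% for the genotypes on the standard diet, with 6 among 15746. They need not hold for homozygotes on the heat-treated diet, where 2 libraries stood apart. Where a group had no count, a fold was taken against 3 counts over its summed depth, a floor that covers counting error only.

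The alternatives were DESeq2 1.42.0, limma voom with quality weights, RLE scaling, no filter and a stricter filter (a mean of at least 1 CPM), mitochondrial and small RNA genes left out (1592 genes), all 30 libraries with and without a tissue term, the replicate number as a block, the animal number as a covariate, only the groups compared in the model, and each library left out in turn. Chosen only after the data were seen were the mitochondrial read share as a covariate, leaving out homozygous heat-treated libraries 1 and 3, and leaving out 4 doubted libraries (those 2, homozygous standard library 5, highest in mitochondrial reads, and heterozygous resistant starch library 4, highest in Slc14a2, of the inner medulla). Up to 100 splits of the libraries into groups of the same sizes, the real one included, were counted for each comparison.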

Results

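The study asked how a heat-treated diet, alone or with added resistant starch, affects the kidney in obese diabetic db/db mice and their heterozygous controls. Mice were randomly assigned to standard chow, a heat-treated diet or that diet with resistant starch (the resistant starch diet). Gene expression in renal cortex was read in 28 libraries: 5 homozygous animals on each of the 3 diets, and 4, 5 and 4 heterozygous animals on the standard, heat-treated and resistant starch diets. Totals ran from 6.03e+06 counts (heterozygous standard library 4) to 2.83e+07 (homozygous resistant starch library 5). In these libraries 16131 genes were tested.

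Genotype was the main axis of the data. A multidimensional scaling used, for each pair of libraries, the 500 genes that differed most between them. Its first dimension held 40.9% of the variance, and homozygous libraries lay at -1.22 to -0.516 and heterozygous ones at 0.579 to 1.23. On the second dimension (9.15%) homozygous heat-treated libraries 1 and 3 lay at 1.46 and 1.25, and no other homozygous library lay above 0.507. The share of reads from the mitochondrial genome was 28.7% ± 7.81 (SD, n = 5), 20.7% ± 5.89 and 24.0% ± 4.6 in homozygotes on the standard, heat-treated and resistant starch diets. In heterozygotes it was 16.5% ± 5.17 (n = 4), 14.7% ± 3.47 (n = 5) and 17.9% ± 4.94 (n = 4). Lepr (chromosome 4, 101717404 to 101815352, GRCm38) was near the floor in all groups, from 1.44 ± 0.679 CPM in homozygotes to 2.82 ± 0.797 CPM in heterozygotes on the resistant starch diet, and did not pass in any comparison. Its largest difference was -1.03 on the log2 scale between those groups (adjusted p = 0.0547).

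**Figure D1:**
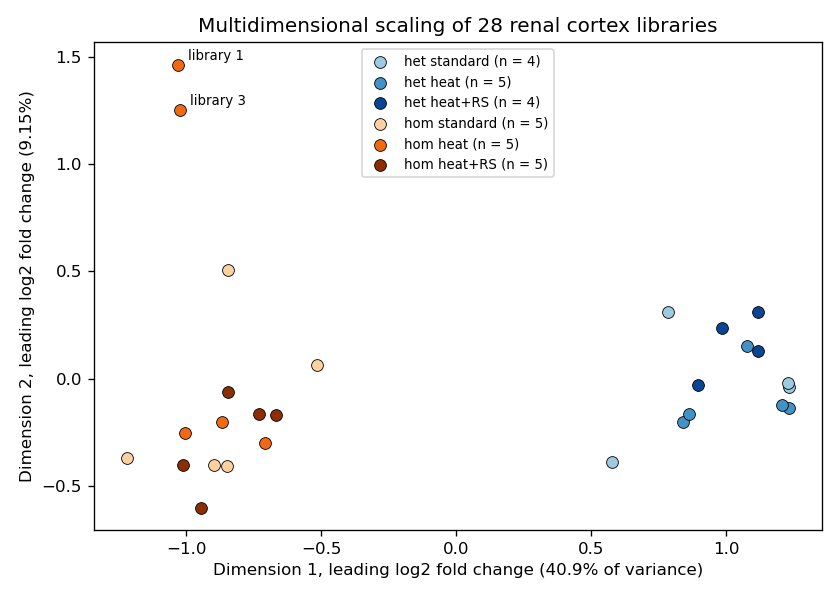
Multidimensional scaling of the 28 renal cortex libraries (axes: leading log2 fold change, dimensions 1 and 2, with 40.9% and 9.15% of the variance), 1 point per library, coloured by group. The genotypes separate on dimension 1.

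The comparison of genotypes asked what the diabetic state changed in the cortex. On the standard diet homozygotes had much more Grem1, a BMP antagonist (19.6 ± 18.2 CPM, n = 5, against 0.120 ± 0.138, n = 4). They had more Bhmt, which remethylates homocysteine (83.6 ± 53.7 against 3.17 ± 2.10 CPM), and more Cyp4a14, a fatty acid hydroxylase (153 ± 85.2 against 9.93 ± 11.2 CPM). They had less Col19a1, a collagen (0.339 ± 0.0375 against 13.8 ± 2.07 CPM), less Cntnap5a, and less Slc22a7, an organic anion transporter (2.45 ± 2.68 against 70.0 ± 33.7 CPM). The complement gene C3 (ENSMUSG00000024164, chromosome 17, 57203970 to 57228136) was 7.08-fold higher (141 ± 33.8 against 19.5 ± 7.97 CPM, adjusted p = 0.0039). Nephrin (Nphs1), of the podocyte slit diaphragm, was 1.91-fold higher (37.5 ± 7.02 against 19.4 ± 4.05 CPM, adjusted p = 0.00241). In total 1632 genes were higher and 1585 lower in homozygotes (edgeR). Log2 fold changes were 6.95 for Grem1, 5.83 for Ugt1a2, 4.59 for Bhmt, 4.37 for Nkx6-2, 4.30 for Gsta2, 3.89 for Ugt1a10, 3.79 for Cyp4a14, 3.58 for Gc and 3.48 for Camk1g. They were -7.09 for Cntnap5a, -5.31 for Col19a1, -5.29 for Neurog2, -5.09 for Ccl28, -4.80 for Alox15, -4.77 for Slc22a7, -4.47 for Igha, -3.90 for Sox2ot, -3.77 for Sec14l3 and -3.72 for Acsm3. For each of these 19 genes 5 of 5 libraries lay beyond the heterozygous median. By over 1.5-fold single libraries moved Cntnap5a (-8.17), Neurog2 (-6.19), Alox15 (-5.48), Slc22a7 (-5.81), Sox2ot (-4.83) and Sec14l3 (-4.70) without homozygous library 1, Grem1 (6.25) without 2, and Ugt1a2 (4.74) and Gsta2 (3.53) without 3. Without heterozygous library 1 Ugt1a10 was at 4.52, without 3 Grem1 at 7.61, Bhmt at 5.30, Nkx6-2 at 3.74, Gsta2 at 5.41 and Cyp4a14 at 4.95, and without 5 Nkx6-2 at 5.16. Ugt1a transcripts share exons, and how the counting treated reads shared by family members is not given. C5ar1 (1.06), Ager (0.68), Havcr1 (-0.43), Lcn2 (3.03), Slc5a2 (0.52) and Col1a1 (-0.05) did not pass.

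Genes with a known sex bias in mouse kidney differed as groups. Of 13 male-biased genes 10 were lower, 1 was higher and 2 did not pass on the standard diet (adjusted over the list alone 11 lower and 1 higher). Their median log2 fold change was -1.92 (adjusted p = 8.11e-07, adjusted p = 0.402 with an estimated correlation, on that side in 5 of 5 libraries). Among them were the androgen-regulated Kap (-2.29), Acsm3 (-3.72), Odc1 (-1.92) and Cyp2e1 (-1.04). Of 9 female-biased genes 5 were higher and 1 lower (6 and 1 adjusted over the list alone; median 1.29, adjusted p = 0.00597, adjusted p = 0.402 with an estimated correlation, 5 of 5 libraries). Markers of the straight proximal tubule were lower in 5 of 10 and higher in 1 (8 and 1 adjusted over the list alone; median -1.52, adjusted p = 0.000244). Distal convoluted tubule markers were higher in 8 of 10 (8 over the list alone, median 0.41, adjusted p = 0.000244). Calb1 was at 1.30. Principal cell markers were higher in 7 of 10 (7 over the list alone, median 0.59, adjusted p = 0.000244), with the water channel Aqp2 at 1.48. For these 3 lists adjusted p = 0.402 with an estimated correlation, with 5 of 5 libraries on that side. Inner medulla scores were -0.55 to 0.97 in homozygotes and -0.42 to 0.57 in heterozygotes, so medulla content stays open. Intercalated cell (8 of 13, 9 over the list alone, median 0.45, adjusted p = 0.00137) and podocyte markers (8 of 16, 9 over the list alone, median 0.42, adjusted p = 0.000523) were higher. Both had adjusted p = 0.509 with an estimated correlation and 5 of 5 libraries higher.

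Injury, matrix and metabolic lists were higher in homozygotes on the standard diet. Tubular injury genes were higher in 13 of 24 (13 adjusted over the list alone; median 0.57, adjusted p = 1.68e-06, adjusted p = 0.402 with an estimated correlation, 5 of 5 libraries). Matrix genes were higher in 10 of 36 and lower in 1 (the same counts adjusted over the list alone; median 0.34, adjusted p = 0.000244, adjusted p = 0.648 with an estimated correlation, 5 of 5 libraries). Glucose-handling genes were higher in 9 of 26 and lower in 1 (10 and 2 adjusted over the list alone; median 0.22, adjusted p = 0.00879, adjusted p = 0.509 with an estimated correlation, 5 of 5 libraries). NRF2 targets went both ways, 11 higher and 5 lower of 29 (17 and 5 adjusted over the list alone; median 0.28, adjusted p = 0.00997, adjusted p = 0.509 with an estimated correlation, 5 of 5 libraries). B and plasma cell genes were lower in 5 of 10 (7 adjusted over the list alone; median -1.65, adjusted p = 0.000981, adjusted p = 0.509 with an estimated correlation, 5 of 5 libraries). Cell cycle genes (7 higher and 1 lower of 30, 7 and 1 adjusted over the list alone; median 0.52, adjusted p = 0.00193, 4 of 5 libraries) were higher. So were immediate early genes (3 higher of 22, 3 adjusted over the list alone; median 0.32, adjusted p = 0.0109, 5 of 5 libraries). These lists had adjusted p = 0.648 and 0.738 with an estimated correlation. Nuclear respiratory chain genes were higher in 20 of 76 (22 adjusted over the list alone; median 0.09, adjusted p = 0.00118, adjusted p = 0.797 with an estimated correlation, 5 of 5 libraries). The lists of mitochondrially encoded, ribosomal and unfolded protein response genes were called with medians of 0.52, 0.08 and -0.15 and adjusted p = 0.711, 0.797 and 0.797 with an estimated correlation, beside the higher mitochondrial read share of this group. Those 3 calls ended without single libraries. The first ended without homozygous library 5 or heterozygous library 4 or 5 (adjusted p 0.0579 to 0.092), and the second without homozygous library 1, 2 or 3 or heterozygous library 4 or 5 (0.0722 to 0.124). The third ended without homozygous library 3 or 4 or heterozygous library 1, 4 or 5 (0.0615 to 0.174). With the mitochondrial read share as a covariate 1564 genes passed.

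**Figure D2:**
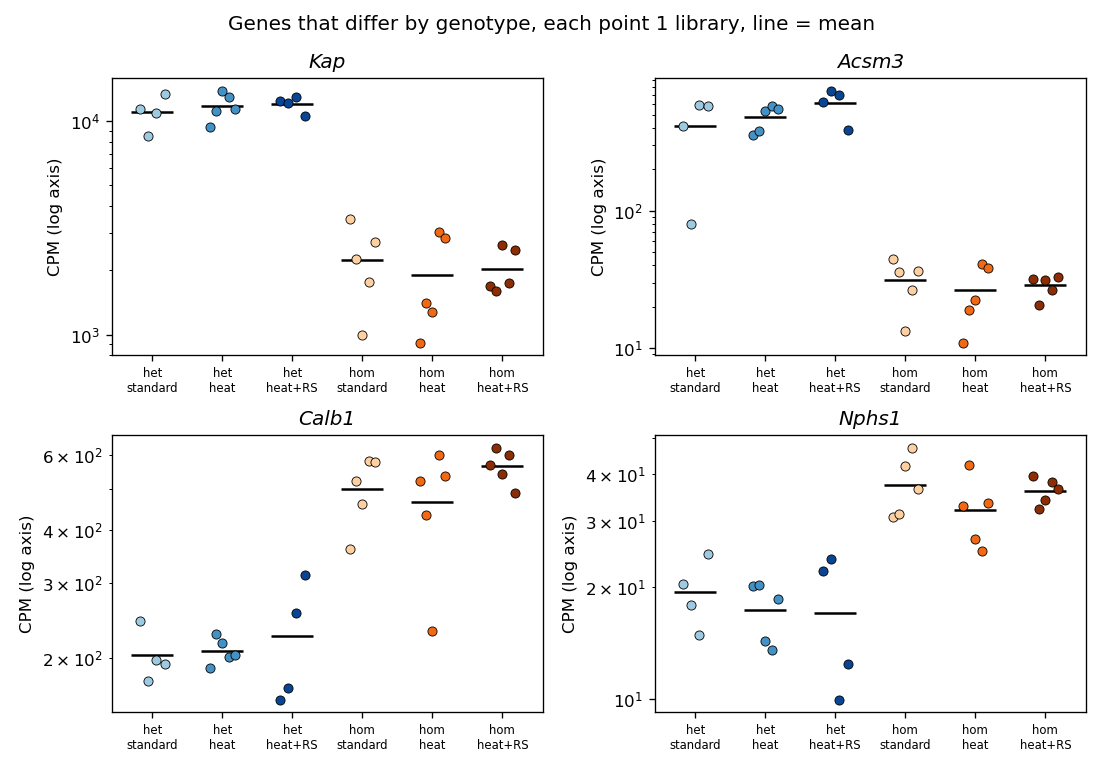
CPM (log axis) of Kap, Acsm3, Calb1 and Nphs1 in the 6 groups, 1 point per library with a line at the mean. Kap and Acsm3 were lower and Calb1 and Nphs1 higher in homozygotes on each diet.

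On the heat-treated diet the genotypes differed in many of the same genes (r = 0.80 across genes with the log2 fold changes on the standard diet; 1212 genes higher and 1222 lower on both diets, where 270 and 234 would be shared by chance). C3 was 41.0-fold higher in homozygotes (601 ± 794 against 14.7 ± 1.77 CPM, n = 5 each, adjusted p = 2.47e-06, 5 of 5 libraries). Lipocalin 2 (Lcn2), a marker of tubular injury, was 127-fold higher (23.5 ± 35.4 against 0.162 ± 0.165 CPM, adjusted p = 0.000242, 5 of 5 libraries). Homozygous libraries 1 and 3 held the highest values of both: on the log2 scale C3 was at 5.36 and at 4.18 without library 3, Lcn2 at 6.98 and at 5.63 without it, and each at 3.04 without both (Lcn2 7.82 without heterozygous library 3). The acute phase gene Saa1 was read in no heterozygous library and was at least 151-fold higher in homozygotes, against a floor of 3 counts over the group, with 4 of 5 libraries above it (at least 28.5-fold without homozygous library 3). Reads of Saa1 can be shared with its paralog Saa2. In total 2673 genes were higher and 2377 lower (edgeR). After Saa1 and Lcn2, log2 fold changes were 7.08 for Grem1, 6.29 for Cxcl2, 6.23 for Muc13, 6.19 for Ugt1a2, 5.99 for Cyp4a14, 5.90 for Gsta2, 5.70 for Ugt1a9 and 5.39 for Bhmt. Decreases were -7.19 for Cntnap5a, -6.43 for Neurog2, -5.75 for Alox15, -5.09 for Col19a1, -4.98 for Slc22a7, -4.37 for Ccl28, -4.18 for Acsm3, -4.02 for Nwd2, -3.91 for Tmprss9 and -3.91 for Angptl7. For 18 of these 20 genes 5 of 5 libraries lay beyond the heterozygous median (Saa1 and Cxcl2 4 of 5). Without homozygous library 1 Muc13 was at 5.57, Ugt1a2 at 5.36 and Ugt1a9 at 5.05, without 3 Neurog2 at -7.02, without heterozygous library 1 Grem1 at 7.73, and without 4 Muc13 at 7.75 and Ugt1a9 at 7.22. Nphs1 was higher (0.90, adjusted p = 0.00104), and Ager (0.56) and Slc5a2 (-0.12) did not pass. Single libraries ended 3 calls. C5ar1 (1.93, adjusted p = 0.0118) ended without homozygous library 1 (1.32, adjusted p = 0.0994). Havcr1, the kidney injury molecule (3.57, adjusted p = 0.0217, above the heterozygous median in 2 of 5 libraries), and Col1a1 (1.26, adjusted p = 0.0134) ended without homozygous library 3 (Havcr1 at 0.14; adjusted p = 0.919 and 0.0703). Without homozygous libraries 1 and 3 Havcr1 was called lower in homozygotes (-2.33, adjusted p = 0.0195).

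Chemokine and NF-kB genes were higher in 18 of 24 on this diet (19 adjusted over the list alone; median 1.04, adjusted p = 0.000113, adjusted p = 0.564 with an estimated correlation, 5 of 5 libraries). Cxcl10 was at 2.06. Homozygous libraries 1 and 3 had chemokine scores of 1.30 and 1.96 against -0.21 to 0.05 in the other 3 and -0.31 to -0.19 in heterozygotes. Without them the chemokine (median 0.21), proximal tubule (-0.02) and smooth muscle lists (0.28) were not called (adjusted p = 0.0639, 0.26 and 0.0806). Tubular injury genes were higher in 19 of 24 (21 adjusted over the list alone; median 1.01, adjusted p = 3.28e-09). Matrix genes were higher in 27 of 36 with 1 lower (31 and 1 adjusted over the list alone; median 0.70, adjusted p = 7.06e-09) and immediate early genes in 14 of 22 (19 adjusted over the list alone; median 0.92, adjusted p = 1.15e-06). Each of the 3 lists had adjusted p = 0.389 with an estimated correlation and 5 of 5 libraries on that side. PPAR-alpha targets were higher in 17 and lower in 5 of 38 (18 and 5 adjusted over the list alone; median 0.26, adjusted p = 0.00257, adjusted p = 0.564 with an estimated correlation, 5 of 5 libraries). Male-biased genes were lower in 11 of 13 and higher in 1 (11 and 1 adjusted over the list alone; median -2.24, adjusted p = 1.15e-07) and female-biased genes higher in 6 of 9 and lower in 1 (7 and 1 adjusted over the list alone; median 1.45, adjusted p = 0.0032). Both had adjusted p = 0.389 with an estimated correlation and 5 of 5 libraries on that side. Distal convoluted tubule (7 of 10 higher, 9 adjusted over the list alone; median 0.41, adjusted p = 0.00095) and principal cell markers (6 of 10, 8 adjusted over the list alone; median 0.59, adjusted p = 0.00095) had adjusted p = 0.389 with an estimated correlation. General proximal tubule markers were lower in 7 and higher in 2 of 20 (7 and 3 adjusted over the list alone; median -0.26, adjusted p = 0.0103) and straight segment markers lower in 5 and higher in 1 of 10 (5 and 1 adjusted over the list alone; median -1.38, adjusted p = 0.00412). Both had adjusted p = 0.537 with an estimated correlation. Unfolded protein response genes were lower in 14 and higher in 2 of 25 (15 and 3 adjusted over the list alone; median -0.48, adjusted p = 0.00095, adjusted p = 0.564 with an estimated correlation, 4 of 5 libraries). The other called lists were cell cycle (median 0.70), glucose handling (0.30), ribosomal (0.12) and smooth muscle genes (0.32), with adjusted p = 0.564, 0.537, 0.691 and 0.537 with an estimated correlation. NRF2 targets (median 0.22, adjusted p = 0.537 with an estimated correlation) ended without homozygous library 4 (adjusted p = 0.053) and intercalated cell markers (0.29, adjusted p = 0.596 with an estimated correlation) without homozygous library 2 or 4 or heterozygous library 3 (0.0555 to 0.0766).

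On the resistant starch diet 2035 genes were higher and 1984 lower in homozygotes (edgeR), again with less Kap (-2.56, adjusted p = 1.98e-06) and more Kynu, of tryptophan breakdown (60.3 ± 14.6, n = 5, against 2.70 ± 0.824 CPM, n = 4). C3 was 7.08-fold higher (112 ± 18.3 against 15.8 ± 2.32 CPM, adjusted p = 0.00323, 5 of 5 libraries) and Nphs1 2.15-fold higher (adjusted p = 0.000387, 5 of 5 libraries), while C5ar1 (-0.08), Ager (0.49), Havcr1 (-0.65), Lcn2 (1.02), Slc5a2 (0.61) and Col1a1 (0.79) did not pass. The named increases ran from 5.92 on the log2 scale for Ugt1a2 to 3.64 for Ugt1a1, with Gsta2, Bhmt, Gc, Grem1, Ugt1a10, Kynu, Cyp4a14 and Nkx6-2 between them. Neurog2 was at 0 counts in all homozygous libraries, at least 40.2-fold lower against 3 counts over the group, and other named decreases ran from -7.44 for Cntnap5a to -4.35 for Ctxn3, with Slc22a7, Col19a1, Ccl28, Cyp2b10, Alox15, Slco1a1 and Acsm3 between them. For all 20 genes 5 of 5 libraries lay beyond the heterozygous median. Gc (4.6) was at 5.23 without heterozygous library 1, Grem1 (4.56) at 5.20 and Cyp2b10 (-4.82) at -3.87 without 4, Cyp4a14 (4.31) at 5.06 and Nkx6-2 (3.92) at 4.71 without 5, and Slc22a7 (-5.84) at -6.76 without homozygous library 3. Unfolded protein response genes were lower in 18 of 25 (19 adjusted over the list alone; median -0.64, adjusted p = 5.91e-09, adjusted p = 0.375 with an estimated correlation, 5 of 5 libraries). Cell cycle genes were higher in 18 and lower in 1 of 30 (21 and 1 adjusted over the list alone; median 0.81, adjusted p = 2.1e-06, adjusted p = 0.411 with an estimated correlation, 5 of 5 libraries). Male-biased genes were lower in 11 of 13 (11 adjusted over the list alone; median -2.10, adjusted p = 2.62e-09). Female-biased genes were higher in 6 and lower in 1 of 9 (6 and 1 adjusted over the list alone; median 1.40, adjusted p = 0.00109) and distal convoluted tubule markers higher in 8 of 10 (8 adjusted over the list alone; median 0.53, adjusted p = 2.21e-05). Each of the 3 lists had adjusted p = 0.289 with an estimated correlation and 5 of 5 libraries on that side. Matrix genes (15 higher and 1 lower of 36, median 0.44), podocyte markers (9 higher and 1 lower of 16, median 0.53), glucose-handling genes (11 higher and 1 lower of 26, median 0.32), straight proximal tubule markers (7 lower and 1 higher of 10, median -1.68), intercalated cell markers (6 of 13 higher, median 0.31) and B and plasma cell genes (3 of 10 lower, median -1.40) were called. In that order they had adjusted p = 0.604, 0.458, 0.406, 0.375, 0.604 and 0.604 with an estimated correlation. Adjusted over the list alone, these counts were 18 and 1, 11 and 1, 12 and 1, 9 and 1, 6, and 5. Endothelial and smooth muscle genes were called with medians of 0.18 and 0.21 (adjusted p = 0.604 each with an estimated correlation), and ended without heterozygous library 4 (adjusted p = 0.0689), and without homozygous library 1 or heterozygous library 2 or 4 (adjusted p 0.0518 to 0.0787). Across the diets 855 genes were higher and 905 lower in homozygotes in all 3 comparisons, and 3 were called in all with mixed directions.

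In homozygotes the heat-treated diet was set against the standard diet to ask whether heat processing of food affects the diabetic kidney. No single gene passed, and 2 of the 5 animals on the heat-treated diet had far more inflammatory and injury transcripts than the others. C3 was read at 695 and 1949 CPM in libraries 1 and 3 and at 94.1 to 142 CPM in the other 3, and Lcn2 at 30.4 and 82.6 CPM against 0.828 to 1.76 CPM. Havcr1 was at 65.0 CPM in library 3. The count of 0 (edgeR, smallest adjusted p = 0.0956) stood beside 1793 genes at an unadjusted p under 0.05, 59 genes by DESeq2 and 0 by voom, and the model made 1, 17 and 11 calls without heat-treated library 1, 2 or 5. The smallest p-values were those of Susd3 (35.7 ± 6.69 against 20.9 ± 3.07 CPM, n = 5 each, log2 fold change 0.77), Cldn7 (0.64), Plk3 (1.54), Emx2 (-0.47) and Gpatch11 (-0.42), all with adjusted p = 0.0956. For C3 (2.08, adjusted p = 0.223), Lcn2 (3.40, 0.197), Havcr1 (4.05, 0.247), Col1a1 (1.03, 0.321), C5ar1 (0.86, 0.531), Nphs1 (-0.22, 0.705), Slc5a2 (-0.38, 0.591) and Ager (-0.04, 0.981) the values did not pass.

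Against all other genes, 14 lists were called in this comparison, 11 higher and 3 lower. Chemokine and NF-kB genes were higher (0 of 24 passed, 13 adjusted over the list alone; median log2 fold change 0.78, adjusted p = 6.32e-10, 4 of 5 libraries). Cxcl1 was at 3.35. Immediate early genes (0 of 22, 12 adjusted over the list alone; median 0.48, adjusted p = 9.15e-07, 3 of 5 libraries) were higher. PPAR-alpha targets (0 of 38, 0 adjusted over the list alone; median 0.15, adjusted p = 0.000366, 4 of 5 libraries) and ribosomal protein genes (0 of 75, 17 adjusted over the list alone; median 0.07, adjusted p = 1.11e-05, 3 of 5 libraries) were higher too. These lists had adjusted p = 0.593 with an estimated correlation, and their calls were made without each library in turn. Clock genes were higher in 5 of 5 libraries (0 of 24, 1 adjusted over the list alone; median 0.38, adjusted p = 6.85e-05, adjusted p = 0.406 with an estimated correlation). Mitochondrially encoded genes were lower in 5 of 5 libraries (0 of 7, 6 adjusted over the list alone; median -0.62, adjusted p = 6.85e-05, adjusted p = 0.593 with an estimated correlation), beside the lower mitochondrial read share. The lists of complement (median 0.28, adjusted p = 0.00158), antigen presentation (0.55, 0.000769), macrophage (0.57, 6.85e-05), neutrophil (1.80, 0.0202), tubular injury (0.37, 0.000421) and matrix genes (0.15, 0.0429) were called higher with 2, 3, 3, 5, 3 and 3 of 5 libraries on that side. They had adjusted p = 0.593, 0.846, 0.593, 0.593, 0.593 and 0.88 with an estimated correlation. Adjusted over the list alone, 1, 0, 0, 3, 2 and 0 of their genes passed. Those 6 calls rested on heat-treated libraries 1 and 3. Without library 1 the adjusted p was 0.115 for complement, 0.633 for antigen presentation, 0.195 for macrophage, 0.392 for neutrophil and 0.687 for matrix genes. Without library 3 it was 0.0855 for complement and antigen presentation, 0.125 for neutrophil, 0.265 for tubular injury and 0.505 for matrix genes. Without both libraries (chosen after the data were seen) none of these 6 lists nor the chemokine or immediate early list was called higher (camera), the medians of the 6 turned to -1.05 to -0.09, and C3 stood at -0.23 and Lcn2 at -0.54. Neutrophil genes also ended without standard library 1 or 4 (adjusted p 0.0597 and 0.114), and matrix genes without standard library 1, 3 or 4 (0.0931 to 0.116). Genes of short-chain fatty acid receptors and transport (median -0.13) and podocyte markers (-0.17) were called lower (adjusted p = 0.593 and 0.821 with an estimated correlation). They ended without standard library 2 or 4 or heat-treated library 1 or 3 (0.0758 to 0.383) and without standard library 3 or 4 or heat-treated library 4 (0.0686 to 0.276).

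**Figure D3:**
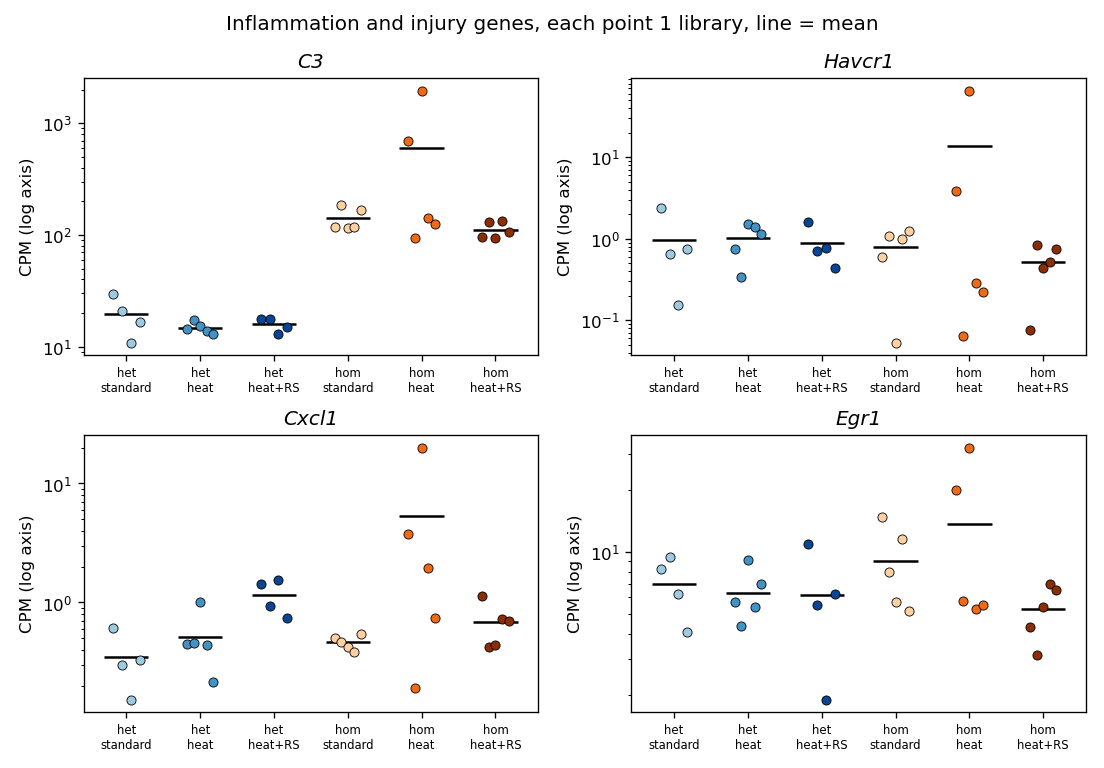
CPM (log axis) of C3, Havcr1, Cxcl1 and Egr1 in the 6 groups, 1 point per library with a line at the mean. In homozygotes on the heat-treated diet libraries 1 and 3 hold C3 at 695 and 1949 CPM.

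Adding resistant starch to the heat-treated diet was tested next in homozygotes. Among the genes that fell were Lcn2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), from 23.5 ± 35.4 to 0.928 ± 0.335 CPM (n = 5 each, adjusted p = 0.0334), and Plk3, a stress kinase, from 16.9 ± 11 to 5.52 ± 1.57 CPM (adjusted p = 0.021). The immediate early Nr4a1 (ENSMUSG00000023034, chromosome 15, 101254269 to 101274795) fell from 10.3 ± 4.65 to 3.59 ± 1.12 CPM (adjusted p = 0.0224) and the cell cycle inhibitor Cdkn1a from 15.7 ± 5.22 to 6.58 ± 1.79 CPM (adjusted p = 0.043). Rising genes included Srd5a1, the steroid 5-alpha reductase, from 9.92 ± 0.959 to 17.1 ± 2.64 CPM (adjusted p = 0.00431), Tnfaip8 from 193 ± 36.8 to 322 ± 21.5 CPM (adjusted p = 0.0186) and Dnajc6, the clathrin-uncoating auxilin, from 26.6 ± 7.29 to 46.0 ± 3.59 CPM (adjusted p = 0.0178). In all 40 genes rose and 54 fell (edgeR), with 2191 at an unadjusted p under 0.05, 292 by DESeq2 and 13 by voom. The other named increases on the log2 scale were Slc17a4 (1.37), Gpr179 (1.16), Nrg4 (0.87), Mcm10 (0.72), Osbp2 (0.70), Syn3 (0.68) and Tln2 (0.63), and the other decreases Serpina3n (-3.59), Egr2 (-2.80), Atf3 (-1.87), Smoc1 (-1.52), Dusp8 (-1.51) and Muc19 (-1.22). For all 20 genes the 5 resistant starch libraries lay on 1 side of the heat-treated median. Without heat-treated library 3 Lcn2 (log2 fold change -4.67) was at -3.31 and Atf3 at -1.0, and without 1 and 3 they were at -0.72 (adjusted p = 0.557) and -0.83 (0.187). C3 was at -2.42 (adjusted p = 0.0539), Havcr1 at -4.57 (0.0949), C5ar1 at -1.42 (0.223), Col1a1 at -0.78 (0.356), Slc5a2 at 0.42 (0.481), Nphs1 at 0.17 (0.756) and Ager at 0.27 (0.787), and did not pass. The count depended on single libraries: 40, 187, 58 and 193 genes passed without heat-treated library 1, 2, 4 or 5, and 34, 23, 12 and 23 without resistant starch library 1, 2, 3 or 5. It was 14 without heat-treated libraries 1 and 3, 4 with only these groups in the model (1 of 20 named genes) and 45 with no filter. Of 22 called genes named 2, Srd5a1 and Dnajc6, kept their call without each library in turn. The other 20 ended without at least 1 of heat-treated libraries 1, 2, 3 and 4 or of resistant starch libraries 1 to 5 (adjusted p 0.0516 to 0.152), Lcn2 among them without any of heat-treated libraries 1 and 3 and resistant starch libraries 1 to 5 (0.058 to 0.0997).

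Among lists, immediate early genes were lower on the resistant starch diet. Egr2, Nr4a1 and Atf3 fell and 19 of 22 did not pass (18 fell adjusted over the list alone; median -0.75, adjusted p = 1.29e-14, adjusted p = 0.286 with an estimated correlation, 5 of 5 libraries), and this was the 1 list called by fry (adjusted p = 0.0252). Tubular injury genes were lower, with Lcn2, Cdkn1a and S100a10 (-0.42) falling and 21 of 24 not passing (10 adjusted over the list alone; median -0.51, adjusted p = 6.59e-07, 5 of 5 libraries). Chemokine and NF-kB genes were lower, with Nfkbia (-0.85, adjusted p = 0.0323) falling and 23 of 24 not passing (17 adjusted over the list alone; median -0.81, adjusted p = 4.11e-09, 4 of 5 libraries). Unfolded protein response genes (Atf3 falling, 24 of 25 not passing, 1 adjusted over the list alone; median -0.20, adjusted p = 8.86e-06, 5 of 5 libraries) and ribosomal genes (0 of 75, 1 adjusted over the list alone; median -0.10, adjusted p = 7.97e-09, 5 of 5 libraries) were lower as well. These 4 lists had adjusted p = 0.535 with an estimated correlation, and all 5 kept their call without each library in turn. Complement (median -0.38, adjusted p = 0.00376), macrophage (-0.63, 0.000122), neutrophil (-3.15, 0.00477) and B and plasma cell genes (-1.67, 0.00132) were called lower, with 4, 3, 4 and 5 of 5 libraries on that side and adjusted p = 0.605, 0.63, 0.535 and 0.535 with an estimated correlation. Adjusted over the list alone 1, 3, 4 and 5 of their genes fell. Without heat-treated library 1 these calls ended at adjusted p 0.088, 0.0914, 0.0819 and 0.14, and that of complement without library 3 at 0.0643. Without libraries 1 and 3 the complement, macrophage and matrix medians turned to 0.05, 0.05 and 0.10, and chemokine, tubular injury, neutrophil, B and plasma cell and proximal tubule genes were not called (adjusted p 0.497 to 0.98). General proximal tubule markers were higher in 5 of 5 libraries (median 0.11, adjusted p = 0.00518, adjusted p = 0.535 with an estimated correlation), a call that ended without heat-treated library 1 (adjusted p = 0.152). Cell cycle (Mcm6 rose, 0.52; median 0.21, 4 of 5 libraries), mitochondrially encoded (median 0.36, 4 of 5 libraries), matrix (-0.14, 4 of 5 libraries) and fatty acid synthesis genes (-0.15, 5 of 5 libraries) were called with adjusted p = 0.63, 0.63, 0.63 and 0.535 with an estimated correlation. They ended without heat-treated library 2 or 4 or resistant starch library 2, 3 or 4 (0.0518 to 0.36), without heat-treated library 4 (0.059), without heat-treated library 1 or 3 or resistant starch library 5 (0.0619 to 0.362), and without heat-treated library 4 or 5 or resistant starch library 1 or 3 (0.0601 to 0.0883).

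Between the resistant starch and the standard diet the homozygous kidneys differed in circadian clock genes, among others. The output genes Dbp and Tef were higher on the resistant starch diet (84.1 ± 30.5 against 16.2 ± 8.03 CPM, adjusted p = 0.0361, and 366 ± 46.5 against 189 ± 37.9 CPM, adjusted p = 0.000946, n = 5 each). The repressors Per3 (66.8 ± 19.2 against 22.4 ± 8.03 CPM, adjusted p = 0.017), Per2 (1.32) and Ciart (3.23) were higher too. The activators Arntl (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126; 6.32 ± 3.54 against 28.1 ± 14.4 CPM, adjusted p = 0.0255) and Npas2 (-2.24) were lower. Of 24 clock genes 7 rose, 3 fell and 14 did not pass (10 and 5 adjusted over the list alone; median 0.31, adjusted p = 0.000345, adjusted p = 0.427 with an estimated correlation, 5 of 5 libraries), and the list was also called by fry (adjusted p = 0.0402). In all 34 genes rose and 31 fell (edgeR), with 1759 at an unadjusted p under 0.05, 193 by DESeq2 and 139 by voom. Further named increases were Bhlhe41 (1.51), Gpr179 (1.43), Lingo4 (1.2), Efna3 (1.2) and Nat8f6 (0.95), and decreases Nr4a1 (-1.73), Ypel2 (-1.35), the lactate transporter Slc16a1 (-1.17), Palm3 (-1.07), Dtx4 (-1.06), Micalcl (-0.96), Ackr3 (-0.96) and Nckap5 (-0.65). All 5 resistant starch libraries lay on 1 side of the standard median for these 20 genes. C3 (-0.34), Lcn2 (-1.27), Havcr1 (-0.51), C5ar1 (-0.56), Ager (0.22), Nphs1 (-0.05), Slc5a2 (0.04) and Col1a1 (0.25) did not pass. The count was 14, 15 and 43 without standard library 1, 2 or 3 and 18, 30, 19 and 33 without resistant starch library 1, 2, 3 or 5, and with only these groups 9 of 21 named genes were called. Of the 21, 4, Tef, Nat8f6, Nr4a1 and Dtx4, kept their call without each library in turn. The other 17 ended without at least 1 of the 10 libraries (adjusted p 0.0518 to 0.206), Arntl among them without standard library 1 or 2 or resistant starch library 1, 2 or 3 (0.0559 to 0.101).

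The other lists called in this comparison, all with adjusted p = 0.991 with an estimated correlation, numbered 6. They were immediate early genes (Nr4a1 fell, 2 adjusted over the list alone; median -0.19, adjusted p = 0.00624, 5 of 5 libraries), antigen presentation (0 of 21; median 0.51, adjusted p = 0.000373, 5 of 5 libraries) and cell cycle (Mcm6 rose, 0.50; median 0.30, adjusted p = 0.00495, 3 of 5 libraries). PPAR-alpha targets (0 of 38; median 0.09, adjusted p = 0.00764, 4 of 5 libraries), unfolded protein response (0 of 25; median -0.20, adjusted p = 0.00248, 5 of 5 libraries) and loop of Henle markers (1 adjusted over the list alone; median -0.25, adjusted p = 0.0158, 4 of 5 libraries) completed them. Of these, the immediate early list kept its call without each library in turn. Antigen presentation ended without resistant starch library 4 or 5 (adjusted p 0.0596 and 0.0642), cell cycle without standard library 3 or resistant starch library 2 (0.456 and 0.264). PPAR-alpha targets ended without standard library 3 or resistant starch library 1 (0.0651 and 0.0867), the unfolded protein response without standard library 1 (0.0861), and loop of Henle markers without standard library 1 or 3 or resistant starch library 2 or 4 (0.0596 to 0.126).

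**Figure D4:**
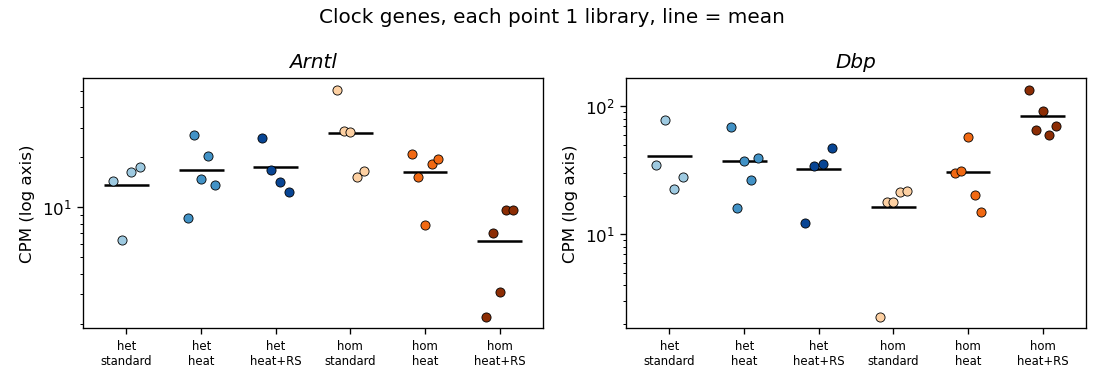
CPM (log axis) of Arntl and Dbp in the 6 groups, 1 point per library with a line at the mean. In homozygotes Arntl was lower (6.32 ± 3.54 against 28.1 ± 14.4 CPM) and Dbp higher on the resistant starch than on the standard diet.

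In heterozygotes the heat-treated diet gave no gene that passed against the standard diet. The smallest p-values were those of Zbtb40 (45.6 ± 3.53 CPM, n = 5, against 32.0 ± 1.11, n = 4; 0.51, adjusted p = 0.0846), Caprin2 (-0.59, 0.709), Palld (0.53, 0.709), the chaperone Hspa8 (0.58, 0.74) and Plch1 (-0.65, 0.74). C3 was at -0.45, Lcn2 at -0.55, Havcr1 at 0.05, C5ar1 at -0.01, Ager at 0.08, Nphs1 at -0.18, Slc5a2 at 0.26 and Col1a1 at -0.28. The count of 0 (edgeR) stood beside 840 genes at an unadjusted p under 0.05, 1 by DESeq2 and 2 by voom. Unfolded protein response genes were higher as a list (0 of 25 passed; median 0.23, adjusted p = 2.45e-06, 4 of 5 libraries). This call was made without each library in turn. The lists of nuclear respiratory (median 0.06), ribosomal (0.05) and erythrocyte genes (0.67) were called higher and those of matrix (-0.18), PPAR-alpha (-0.06), loop of Henle (-0.30), B and plasma cell (-0.36) and smooth muscle genes (-0.14) lower. All 9 lists had adjusted p = 0.971 with an estimated correlation, and adjusted over the list alone 1 gene, of smooth muscle, passed. Lists called numbered 3, 5 and 5 without standard library 1, standard library 5 or heat-treated library 2. The nuclear respiratory call ended without standard library 4 (adjusted p = 0.0549), the ribosomal without standard library 4 or 5 or heat-treated library 2 (0.0622 to 0.293) and the erythrocyte without standard library 1 or 5 or heat-treated library 1 (0.127 to 0.642). Matrix genes ended without standard library 1 or heat-treated library 4 (0.973 and 0.19), PPAR-alpha targets without standard library 1 or 3 or heat-treated library 2 (0.0813 to 0.204) and loop of Henle markers without standard library 1 or 5 or heat-treated library 1, 2 or 5 (0.056 to 0.494). B and plasma cell genes ended without standard library 1, 4 or 5 or heat-treated library 1, 2, 3 or 4 (0.0727 to 0.318) and smooth muscle genes without standard library 1, 3 or 4 or heat-treated library 3 or 4 (0.0531 to 0.279).

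Resistant starch on top of the heat-treated diet raised 5 genes in heterozygotes. Among them were Slc25a22, a mitochondrial glutamate carrier (ENSMUSG00000019082, chromosome 7, 141429744 to 141437892; 29.4 ± 8.48 CPM, n = 4, against 13.1 ± 0.881, n = 5, adjusted p = 0.000181), and Fkbp5, a glucocorticoid-induced chaperone (222 ± 81.3 against 84.3 ± 12.2 CPM, adjusted p = 0.0226). The others were Nr4a3, an orphan nuclear receptor (2.56 ± 1.35 against 0.355 ± 0.271 CPM, adjusted p = 0.0226), Zfp648 (1.31 on the log2 scale, adjusted p = 0.0226) and the peroxisomal Pex11a (0.55, adjusted p = 0.0358). For the 5 genes 4 of 4 libraries lay above the heat-treated median. The count (edgeR) stood beside 1295 genes at an unadjusted p under 0.05, 54 by DESeq2 and 52 by voom. C3 (0.11), Lcn2 (1.30), Havcr1 (-0.34), C5ar1 (0.60), Ager (0.33), Nphs1 (-0.04), Slc5a2 (-0.31) and Col1a1 (-0.31) did not pass. PPAR-alpha targets were higher as a list (0 of 38 passed, 11 adjusted over the list alone; median 0.17, adjusted p = 3.27e-10, adjusted p = 0.708 with an estimated correlation, 4 of 4 libraries). Angptl4 was at 1.65 and Pdk4 at 1.32. Tubular injury genes were higher (0 of 24, 1 adjusted over the list alone; median 0.40, adjusted p = 3.38e-05, adjusted p = 0.834 with an estimated correlation, 4 of 4 libraries). Principal cell (median 0.17, adjusted p = 0.834 with an estimated correlation), podocyte (-0.15, 0.952) and erythrocyte genes (-0.65, 0.952) were called too. Resistant starch library 4 stood apart on inner medulla and papilla markers (score 1.42 against -0.27 to 0.13 in the other 3) and had the lowest podocyte score (-0.76 against -0.51 to -0.05). They ended without heat-treated library 2 or resistant starch library 4 or 5 (0.0655 to 0.16), without heat-treated library 1, 2 or 5 or resistant starch library 4 or 5 (0.0783 to 0.752), and without heat-treated library 1 or 2 or resistant starch library 2, 4 or 5 (0.0512 to 0.54). Slc25a22 kept its call without each library in turn. The other 4 ended without at least 1 of heat-treated libraries 1, 2, 4 and 5 or resistant starch libraries 1, 2 and 4 (adjusted p 0.051 to 0.343), and with all 30 libraries (0.061 to 0.312). Nr4a3 and Fkbp5 ended with only the groups compared (0.0615 and 0.097). In number, 1 gene passed without heat-treated library 1, 2, 4 or 5 or resistant starch library 4, 2 without resistant starch library 2 and 22 without resistant starch library 5.

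Against the standard diet, 1 gene rose on the resistant starch diet in heterozygotes, again Slc25a22 (29.4 ± 8.48 against 14.6 ± 1.5 CPM, n = 4 each, log2 fold change 1.02, adjusted p = 0.00757, 4 of 4 libraries). The next smallest p-values were those of Cdr2 (101 ± 19.3 against 54.4 ± 6.20 CPM; 0.89, adjusted p = 0.0717), Fkbp5 (1.35, 0.0717), Zfp648 (1.23, 0.137) and Ptpn1 (0.39, 0.137). The count (edgeR) stood beside 1129 genes at an unadjusted p under 0.05, 14 by DESeq2 and 2 by voom. C3 (-0.34), Lcn2 (0.75), Havcr1 (-0.29), C5ar1 (0.59), Ager (0.41), Nphs1 (-0.22), Slc5a2 (-0.05) and Col1a1 (-0.59) did not pass. Unfolded protein response (median 0.23, adjusted p = 2.97e-05, 3 of 4 libraries) and tubular injury genes (2 adjusted over the list alone; median 0.23, adjusted p = 0.00135, 4 of 4 libraries) were called higher without each library in turn. PPAR-alpha (0.09, 3 of 4 libraries), clock (0.09), principal cell (0.24) and male-biased genes (0.38) were called higher and B and plasma cell genes (-0.63) lower, the last 4 with 4 of 4 libraries on that side. All 7 lists had adjusted p = 0.637 with an estimated correlation. The gene's call ended without standard library 1 or 3 or resistant starch library 4 (adjusted p 0.0729 to 0.0979). It also ended with all 30 libraries, with or without a tissue term (0.0814 and 0.0867), with only the groups compared (0.265) and without 4 doubted libraries (0.0868), and 18 genes passed without resistant starch library 5. Lists called numbered 12, 12, 11 and 4 without standard library 3 or resistant starch library 1, 2 or 5. PPAR-alpha targets ended without resistant starch library 5 (0.0951), clock genes without standard library 4 or 5 or resistant starch library 4 or 5 (0.122 to 0.238). Principal cell markers ended without resistant starch library 4 (0.0749), the library high in inner medulla markers, male-biased genes without standard library 3 (0.0546) and B and plasma cell genes without standard library 4 or 5 or resistant starch library 5 (0.052 to 0.0951).

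Whether the diets acted differently in the genotypes was tested by interaction. For the heat-treated diet 0 genes passed (edgeR, smallest adjusted p = 0.474, 1257 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by voom). The smallest p-values were those of Sema7a (0.98), Atp12a (2.59), Cgnl1 (-0.49), Micall1 (0.45) and Slc22a3 (2.06), all with adjusted p = 0.474. The differences were 2.53 for C3, 4.01 for Havcr1, 3.95 for Lcn2, 1.31 for Col1a1, 0.87 for C5ar1, -0.12 for Ager, -0.04 for Nphs1 and -0.64 for Slc5a2, none of which passed. As lists, chemokine and NF-kB genes (2 adjusted over the list alone; median difference 0.79, adjusted p = 1.03e-06) and PPAR-alpha targets (0.22, adjusted p = 1.5e-05) were shifted up in homozygotes relative to heterozygotes. In all 15 lists were called, 10 up and 5 down, all with adjusted p = 0.788 with an estimated correlation, with 13 of them ended by single libraries, written here as genotype (hom, het), diet (std, heat, RS) and number. B and plasma cell genes (1.16, 3 adjusted over the list alone) ended without hom heat 1 (adjusted p = 0.126), and immediate early (0.60) and nuclear respiratory genes (-0.07) without hom heat 3 (0.0532 and 0.342). Matrix genes (0.29) ended without het std 1 (0.154), clock genes (0.34) without het std 3 (0.0875) and mitochondrially encoded genes (-0.57) without het std 4 (0.0672). Antigen presentation (0.63) ended without hom heat 1 or 3 or het std 4 (0.0734 to 0.311), and tubular injury genes (0.44) without hom heat 3 or het std 1 (0.0856 to 0.232). Proximal tubule genes (-0.16) ended without hom heat 1 or 3, het std 1 or het heat 1 (0.0579 to 0.195). Macrophage genes (0.42) ended without hom std 3, hom heat 1 or 3 or het std 1 or 4 (0.0711 to 0.371). Complement genes (0.28) did so without hom std 3 or 4, hom heat 1 or 3, het std 1 or 4 or het heat 4 (0.0672 to 0.232). For podocyte genes (-0.20) these were hom std 3 and 4, hom heat 3, 4 and 5, het std 3 and 4 and het heat 1, 2 and 5 (0.0532 to 0.282). For unfolded protein response genes (-0.16) they were hom std 1, 2 and 5, hom heat 1 and 2, het std 3 and het heat 3 and 5 (0.0611 to 0.195). Lists called numbered 7 without hom heat 3 or both hom heat 1 and 3. Without both, chemokine genes were not called (adjusted p = 0.281), and the antigen presentation, macrophage, complement and nuclear respiratory medians turned to -0.29, -0.21, -0.01 and 0.03. In number, 1 gene passed without hom heat 5.

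For resistant starch on the heat-treated diet the genotypes differed in 80 genes, 33 with a more positive and 47 with a more negative effect in homozygotes (edgeR; 1959 at an unadjusted p under 0.05, 277 by DESeq2 and 64 by voom). Named by rule were Dnajc6 (1.17, adjusted p = 0.00884), Tnfaip8 (1.14, 0.00884), Tln2 (1.05, 0.0144), Srd5a1 (0.97, 0.00905) and Veph1 (0.87, 0.0144) with positive differences, and Egr2 (-4.72, 0.0102), Nr4a3 (-4.16, 0.0042), Inhbb (-2.73, 0.0299), Cdkn1a (-2.48, 0.00884) and Plk3 (-2.29, 0.0169) with negative ones. C3 (-2.53), Lcn2 (-5.97), Havcr1 (-4.23), Col1a1 (-0.47), C5ar1 (-2.02), Ager (-0.06), Nphs1 (0.21) and Slc5a2 (0.73) did not pass. Tubular injury genes were shifted down in homozygotes relative to heterozygotes (1 of 24 passed, Cdkn1a, and 8 adjusted over the list alone; median difference -1.11, adjusted p = 3.15e-10). So were immediate early genes (1 of 22, Egr2, and 11 adjusted over the list alone; -0.94, adjusted p = 3.51e-11). Chemokine and NF-kB genes (8 adjusted over the list alone; -0.90, adjusted p = 7.87e-08) and PPAR-alpha targets (5 adjusted over the list alone; -0.23, adjusted p = 1.45e-05) were shifted down. In all 15 lists were called, 3 up and 12 down, and 6 of them were called without each library in turn. Fatty acid synthesis (-0.25) and unfolded protein response genes (-0.20) completed those 6. Proximal tubule (0.15) and neutrophil genes (-3.66, 2 adjusted over the list alone) ended without hom heat 1 (adjusted p 0.0717 and 0.0652), and ribosomal genes (-0.08) without hom heat 4 (0.0963). Podocyte genes (0.23, Clic5 passing at 0.67) ended without hom heat 4 or het RS 4 or 5 (0.0538 to 0.171), and principal cell genes (-0.26) without hom heat 1, 2 or 4 or het RS 4 (0.0634 to 0.0995). Matrix genes (-0.19) ended without hom heat 1 or 3, het heat 4 or 5 or het RS 1 (0.0619 to 0.164). Macrophage genes (-0.58) did so without hom heat 1 or 3, hom RS 1, het heat 4 or het RS 5 (0.0538 to 0.391). For NRF2 targets (-0.12) these were hom heat 1, 2 and 4, hom RS 5, het heat 4 and het RS 1 and 4 (0.0521 to 0.073). For erythrocyte genes (0.93) they were hom heat 2, 3, 4 and 5, hom RS 3, het heat 1 and 2 and het RS 2, 4 and 5 (0.0521 to 0.291), and for Clic5 hom heat 1 and 3, hom RS 2 to 5, het heat 1, 2, 3 and 5 and het RS 1, 2 and 4 (0.0505 to 0.0833). Over all 15 lists the adjusted p with an estimated correlation was 0.393 to 0.647. The count was 49, 145 and 224 without hom heat 1, 2 or 5, 46 without hom RS 3, 46 and 53 without het heat 1 or 5, and 41 without het RS 4. Without both hom heat 1 and 3 it was 41 too, and the macrophage and matrix medians turned to 0.15 and 0.02. Tubular injury genes were then at -0.40 and chemokine genes at -0.16, and proximal tubule (adjusted p = 0.457) and neutrophil genes (-0.93, 0.387) were not called. Inhbb was at -2.11 without hom heat 3 and ended without hom RS 1 or 3, het heat 1, 2 or 4 or het RS 1 or 4 (adjusted p 0.0502 to 0.0967).

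Across the 16131 genes in homozygotes, the effect of the heat-treated diet and that of resistant starch on top of it were negatively related (Pearson r = -0.57, covariance -0.0334). Both effects share the heat-treated libraries, and genes are not independent replicates. In 1000 simulated sets with no effect r averaged -0.48 (-0.94 to 0.50), and 186 had a covariance as low as seen. With separate heat-treated libraries for the effects, in 20 divisions of the group, the median r was -0.096 (-0.24 to 0.093, negative in 14 of 20).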

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

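Chosen only after the result was seen were the test of sequencing depth and the test without homozygous heat-treated libraries 1 and 3. Within groups, 18 of 276 tests placed 1 library far from the others, where chance does so in about 1 in 20. In homozygotes on the standard diet these were the mitochondrial read share of library 5 (42.2% against 22.9 to 28.3%), Lcn2 and the chemokine score of library 2 (5.49 CPM against 0.804 to 1.54, and 0.49 against -0.29 to -0.12). In the same group they were Dbp, Slc22a7 and Cntnap5a of library 1 (2.26 CPM against 17.7 to 21.9, 7.19 against 0.924 to 1.85, and 0.302 against 0 to 0.0770), Bhmt of library 3 (177 CPM against 41.4 to 71.2) and Zbtb40 of library 4 (28.4 CPM against 34.5 to 35.8). Susd3 stood apart in homozygous heat-treated library 5 (23.9 CPM against 37.0 to 39.9), Havcr1 in library 3 of that group (65.0 CPM against 0.0637 to 3.89) and Slc22a7 in homozygous resistant starch library 3 (3.69 CPM against 0.210 to 0.981). In heterozygotes on the standard diet Fkbp5 stood apart in library 5 (85.1 CPM against 87.9 to 88.2) and the matrix score in library 1 (0.31 against -0.43 to -0.34). On the heat-treated diet the mitochondrial read share and Cdr2 did so in library 2 (20.8% against 12.5 to 14.2%, and 77.7 CPM against 55.5 to 61.0). On the resistant starch diet these were Camk1g and the male-biased score in library 5 (0.248 CPM against 0.420 to 0.438, and 1.03 against 1.37 to 1.38) and the immediate early score in library 1 (0.094 against -0.23 to -0.20).

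Interaction tests called 15 lists for the heat-treated diet (camera, preset correlation), of which 13 ended without single libraries, with no list called by fry or with an estimated correlation and no gene (counts below). For resistant starch 80 genes and 15 lists were called, with differences (homozygous minus heterozygous, log2) of 1.17 for Dnajc6, 1.14 for Tnfaip8, 1.05 for Tln2, 0.97 for Srd5a1, 0.87 for Veph1, -4.72 for Egr2, -4.16 for Nr4a3, -2.73 for Inhbb, -2.48 for Cdkn1a and -2.29 for Plk3. Dnajc6 lies on chromosome 4 at 101496648 to 101642799, within 10 Mb of Lepr.

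In homozygotes 8 lists of inflammation and injury were called higher on the heat-treated than on the standard diet, and the highest C3, Lcn2 and Havcr1 values came from 2 of 5 animals. Without libraries 1 and 3 of the heat-treated group 0 of the 8 lists were still called (camera), with the medians of 7 below 0 (-1.05 to -0.02). But those libraries were picked by their values, which lowers the rest, and standard library 2, also high, was kept. So a smaller response shared by all 5 animals stays open. Sequencing depth was argued against, since libraries 1 and 3 had the group's highest and lowest totals (2.67e+07 and 8.34e+06 counts) and both scored above the other 3 in 8 of the 8 lists. Library 4, with 2.66e+07 counts, had a chemokine score of 0.05 against 1.30 in library 1. Immune cells as the whole cause stayed open: of the epithelial genes tested (Krt7, Krt8, Krt18, Krt19 and Sox9) 2, Krt18 (16.3 and 27.8 CPM, others at most 15.9) and Krt19 (4.53 and 4.88 CPM, others at most 4.41), were higher in both libraries than in each of the other 13 homozygous libraries. Injury or infection in those 2 animals, unrelated to or enhanced by diet, may underlie the pattern, and was not tested.

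Splits of the libraries were counted for each comparison, the real one included. For genotype, 1 of 100 splits gave as many genes on each diet (3217 against a highest other of 1750 on the standard, 5050 against 1943 on the heat-treated and 4019 against 2395 on the resistant starch diet), so chance was excluded. In homozygotes chance stayed open for resistant starch against the heat-treated diet (2 of 100 splits, 94 genes). The highest other, heat-treated libraries 1 to 3 with resistant starch libraries 4 and 5 against the rest, called 197 and points to sample structure. Against the standard diet no other split called as many (1 of 100, 65 genes, highest other 46). For the heat-treated against the standard diet the test was void, as any split matches 0 genes (edgeR, 100 of 100, other counts above). There another split, standard libraries 1, 2 and 5 with heat-treated libraries 4 and 5 against the rest, called 658 genes. What it reflects was not tested. In heterozygotes chance stayed open for resistant starch against the heat-treated diet (4 of 100, 5 genes, highest other 11, with the 4 lowest animal numbers apart). So it did against the standard diet (4 of 35, 1 gene, highest other 1). For the heat-treated against the standard diet the test was void, as any split matches 0 genes (edgeR, 100 of 100, other counts above, highest other 1). For the interactions chance stayed open for resistant starch (2 of 100, 80 genes), where the highest other split, with 521 genes, points to sample structure. For the heat-treated diet the test was again void at 0 genes (edgeR, 100 of 100, 1257 at an unadjusted p under 0.05, 0 by DESeq2 and voom, highest other 3).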

How the results depend on the processing

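Chosen only after the data were seen were the mitochondrial read share as a covariate and the settings without homozygous heat-treated libraries 1 and 3 and without 4 doubted libraries. Over the planned and added alternatives other than leaving out single libraries, values of named genes kept their direction and side of the threshold in 5023 cases, passed no longer in 220, passed newly in 67 and reversed in 35. For called lists these were 623, 287, 0 and 35, and counts stayed within 1.5 times in 167 cases, were lower in 41, higher in 25 and, for 1 value, moved. With single libraries left out, the cases were 4018 kept, 275 no longer and 39 newly passing for genes, 1354 kept and 207 no longer called for lists, and 194 within 1.5 times, 37 lower and 13 higher for counts. For the changes below the cause was not tested, except that a setting with fewer libraries also has less power. An estimated correlation gave 0 lists in each of the 11 comparisons, and fry 0, 1 and 1 in homozygotes (heat-treated against standard, resistant starch against heat-treated, resistant starch against standard), 0, 0 and 0 in heterozygotes, 15, 20 and 15 for genotype on the 3 diets, and 0 in both interactions. The replicate block gave 3 genes and 9 lists for resistant starch against the heat-treated diet in heterozygotes, and libraries of the same number were little more alike than others (mean r 0.032 over 65 pairs against -0.0081 over 261, with 21.5% and 17.2% above 0.1), and the design was not taken as paired.

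DESeq2 gave 59, 292 and 193 genes in homozygotes, 1, 54 and 14 in heterozygotes and 277 for the resistant starch interaction. Voom gave 13 and 139 for resistant starch against the heat-treated and the standard diet in homozygotes and 2, 52 and 2 in heterozygotes. With no filter the counts were 45 and 35 for these 2 homozygous comparisons and 1 for the heat-treated diet in heterozygotes. With only the groups compared, resistant starch against heat-treated gave 4 in homozygotes and 9 in heterozygotes, and against standard 0 in heterozygotes. With all 30 libraries, with or without a tissue term, the heterozygous comparisons gave 1, 1 and 0, and without the term the resistant starch interaction gave 39. The animal number as a covariate gave 3 for resistant starch against heat-treated in heterozygotes. With the mitochondrial read share as a covariate the counts were 3 genes and 13 lists for resistant starch against standard in heterozygotes, 1564 genes for genotype on the standard diet and 131 for the resistant starch interaction. Without homozygous heat-treated libraries 1 and 3 they were 8 lists for heat-treated against standard, 14 genes for resistant starch against heat-treated and 106 against standard in homozygotes. There were also 2 and 21 genes for heat-treated against standard and resistant starch against heat-treated in heterozygotes, 7 lists for the heat-treated interaction and 41 genes for the other. Without 4 doubted libraries they were 30 genes, and 118 genes with 11 lists, for resistant starch against heat-treated and against standard in homozygotes. There were 2 and 0 genes for heat-treated and for resistant starch against standard and 3 lists for resistant starch against heat-treated in heterozygotes, 5 lists for the heat-treated interaction and 29 genes for the other. With separate heat-treated libraries for each effect the relation of the 2 diet effects fell from -0.57 to -0.096.

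With single libraries left out, genes ranged from 0 to 17, 12 to 193 and 14 to 88 in homozygotes (comparisons in the order above). They ranged from 1 to 22 and 0 to 18 for resistant starch against heat-treated and standard in heterozygotes, 0 to 1 for the heat-treated interaction and 41 to 224 for the other. Lists ranged from 9 to 19 and 4 to 10 in homozygotes for heat-treated and resistant starch against standard, 3 to 9, 2 to 7 and 4 to 12 in heterozygotes, and 7 to 18 for the heat-treated interaction.

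Reversed values follow, as log2 fold changes or list medians. Without homozygous heat-treated libraries 1 and 3, heat-treated against standard in homozygotes gave -0.23 for C3, -0.54 for Lcn2, -1.85 for Havcr1, -0.34 for H2-Aa, -0.12 for Fcgr3, -1.07 for S100a9, -1.02 for Csf3r, -0.087 for complement, -0.096 for matrix, -0.10 for tubular injury, -0.45 for antigen presentation, -0.16 for macrophage and -1.05 for neutrophil genes. Without 4 doubted libraries these were -0.16, -0.67, -1.66, -0.43, -0.088, -1.32, -1.16, -0.056, -0.10, -0.077, -0.61 (adjusted p = 0.00156, called lower), -0.20 and -1.24, with -0.069 for H2-D1, -0.056 for chemokine and 0.091 for immediate early genes, a list whose test turned downward while its median did not. Voom gave -0.35 for Havcr1 and -0.21 for Csf3r. For resistant starch against heat-treated in homozygotes, the settings without libraries 1 and 3 and without 4 doubted libraries gave 0.20 and 0.20 for Cfi, 0.12 and 0.11 for Col3a1, 0.087 and 0.084 for Mrc1, 0.053 and 0.050 for complement, 0.10 and 0.10 for matrix and 0.053 and 0.050 for macrophage genes. For genotype, the mitochondrially encoded list on the standard diet was at -0.0045 with the mitochondrial read share as a covariate, and Havcr1 on the heat-treated diet at -2.33, -2.33 (adjusted p = 0.0195 and 0.0225, called lower) and -1.22 without libraries 1 and 3, without 4 doubted libraries and by voom. For the heat-treated interaction the 2 settings gave -0.33 and -0.44 for Cd74, -0.068 and -0.11 for Mrc1, -0.11 and -0.079 for Fcgr3, -0.014 and -0.018 for complement, 0.0057 (where the test turned and the median did not) and -0.061 for tubular injury, -0.29 and -0.44 for antigen presentation, 0.034 and 0.014 for nuclear respiratory and -0.21 and -0.30 for macrophage genes. The second gave -0.018 for Tapbp and 0.0023 for immediate early genes, again a turn of the test alone. For the resistant starch interaction they gave 0.058 and 0.026 for Mrc1 and 0.15 and 0.14 for macrophage genes, and the first gave 0.022 for matrix genes.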

Other observations

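Chosen only after the result was seen were both tests of the clock genes and the test for female animals. The 2 libraries labelled whole kidney had 43.8 and 33.1 CPM of Aqp2 (heterozygous cortex 30 to 81.8) and 0 and 0.204 of Slc14a2 (0 to 13.6).

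The clock genes that differed between the resistant starch and the standard diet in homozygotes may reflect when each animal was sampled. Deviations of Arntl and Dbp from their group means were opposed across the 28 libraries (Pearson r = -0.82, Spearman r = -0.87, permutation p = 1e-05 each, the smallest that 100000 permutations can give), as they would be if animals of the same group differed in clock phase. Without the 2 farthest libraries r was -0.81, and it was -0.75 in homozygotes and -0.97 in heterozygotes. Whether resistant starch shifted the clock alike in both genotypes stays open. The 7 clock genes tested were at -2.24 to 3.23 in homozygotes and -0.36 to 0.37 in heterozygotes, and all 7 differed (unadjusted p 4.98e-05 to 0.0187, 0.000526 for Arntl, edgeR model of n = 28 libraries), but they were picked by their calls in homozygotes, which favours a difference. The time of sampling is not given in the sources used here, so a difference in sampling time and a diet effect on the clock stay open.

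For the genotype calls, variants carried along with the db allele were tested as a cause. Within 10 Mb of Lepr, 33 of 116 tested genes were called on the standard diet (28.4%, against 19.9% elsewhere, ratio 1.43, Fisher's exact p = 0.0263). The ratio was 1.24 (Fisher's exact p = 0.0876) on the heat-treated and 1.07 (p = 0.667) on the resistant starch diet. Passenger variants may account for a few calls near Lepr and stay open there. The lower male-biased and higher female-biased genes of homozygotes were tested for female animals, which was argued against, since 28 of 28 libraries had the male pattern, with Xist at 0.101 to 0.990 CPM and 4 Y-linked genes summing to 182 to 239 CPM. Hormone levels were not tested.

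Several lists were called in no comparison, among them receptors of advanced glycation end products with glyoxalases, the renin-angiotensin system, cholesterol synthesis, interferon response, bile acid, T cell, adipocyte and inner medulla genes. For genotype on the 3 diets, 4, 6 and 2 of the 19 glycation genes were higher and 4, 7 and 5 lower (adjusted p = 0.990, 0.883 and 0.483 for the list by camera).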
